A study of Mus musculus with 2 samples.

How the data were processed

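Incisor pulp of CD1 mice aged 5 days was dissociated 24 h after an injection of EdU (3.3 µg for each g of weight), and EdU-positive cells were sorted and used for chromatin immunoprecipitation, per the labels' protocols. There was 1 library for H3K4me3 and 1 for H3K27me3. An input library was not used for these marks, per the series' design text. Each library forms its own group, named by its antibody target in the labels.

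The submitters' processing notes name BWA, an aligner, SICER, which joins enriched windows into islands of broad signal, and the mouse build mm10. Their versions and the window, gap and significance settings of SICER are not given in the sources used here. Per the file headers, the authors deposited for each mark a track of summits and a track of islands, and a joint track of active regions. Each summit has a score, deposited by the authors as a whole number and named there as the height at the summit. The scaling of these score values between the 2 libraries is not given in the sources used here, so heights were used only to describe, rank and filter islands within a mark. All islands (100%) had a width 1 bp short of a multiple of 200 bp, so positions are resolved to about 200 bp. The 21438 active regions were identical to the 21438 intervals formed by joining the islands of both marks and were not used as a separate measurement. Signal tracks were not used here.

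The files give called islands and no read counts, so the depth per library is unknown and no interval or detection limit was set for a single island. A weakly marked place can be missing where a library was shallow, and without an input library regions of high mappability or copy number can be called in both marks. With 1 library per mark there is no replicate spread, no group comparison was tested and no p-value was computed. Exact binomial (Clopper-Pearson) 95% intervals were computed for shares and cover counting over genes or islands only; neighbouring genes are not independent.

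Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly called mm10, with 1 start and 1 end per gene and 21631 protein-coding genes on the autosomes and X. The planned windows around transcription start sites were replaced by windows of 1 kb either side of both annotated gene ends, because this table gives no strand and no transcripts. A gene was called marked where an island of the mark overlapped either window by at least 1 bp, and its island is the widest one that did. Positions are 1-based on mm10. The Y chromosome was left out of comparisons between genes. All 489 listed symbols were found in the table, older symbols through its synonyms.

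Islands of the 2 marks were compared by overlap of at least 1 bp, and with 1000 placements of the H3K27me3 islands at random on their own chromosome, between the first and the last annotated gene or island. Each of 24 gene lists was compared with 10000 random lists of equal size drawn from all protein-coding genes, and the median width of its marked members with random lists of genes carrying that mark, where at least 5 members did. A percentile is the share of random lists below the list, with ties counted at 50%. The lists cover anchor genes of the theme, dental and cranial mesenchyme factors, odontoblast genes, mesenchymal stem cell and pericyte markers, cell cycle genes and kinase inhibitors, Polycomb complexes 1 and 2, Wnt ligands, receptors and antagonists, hedgehog, FGF and BMP, and Notch pathways, Hox genes, regulators of other lineages, pluripotency genes, markers of epithelium, endothelium, blood, nerve and of cartilage, fat and muscle, and ribosomal and tissue-restricted comparators.

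The lists, the main comparisons, most alternatives and the rule for named genes were fixed before the data were examined. By that rule the text draws its names from every anchor gene, up to 4 members of each list per promoter state in list order (all members of a state with 6 or fewer), the protein-coding genes under the 10 widest islands of each mark (up to 4 per island) and those under the 5 islands with the highest summits. Some genes that the rule takes are not reported here. Gene families and gene-free islands in the closing section were picked after their values were seen. The limits for percentiles, the middle 95% of random lists, were set after the files were opened and before percentiles were computed. Comparisons of list pairs, gene families by symbol, and the alternatives based on the whole gene, on genes with free ends, on the same end and on gene length were added after seeing the data. So were some tests of the closing section, which are named there.

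Alternatives planned at the start were windows of 500 bp and 2.5 kb, a window covered to 50% or more, overlap of at least 50% of the shorter island, islands within 1000 bp merged, autosomes only, summed island length within 5 kb, other definitions of distance from genes, and the higher-summit set of 50% of islands per mark. The higher-summit set shortens each list by construction, and its H3K4me3 and H3K27me3 thresholds are not equivalent. The mark calls and percentiles were tested on simulated data for 21631 genes. For each mark, 100% of the genes with an island planted over their annotated start were called marked. The planted islands lay inside the searched window, so this checks the code only. The share of other genes called marked was not measured. Of 400 lists of 25 random genes, 16 (4%) fell outside the limits. Marks were drawn there gene by gene, so lists whose genes share islands were not simulated. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.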

Results

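Histone methylation was mapped in recently dividing cells of the mouse incisor pulp, the soft core of a tooth that grows throughout life. Pups of the CD1 strain, 5 days old, were given EdU at 3.3 µg per g body weight, a thymidine analogue built into DNA during replication, and the pulp was taken 24 h later. EdU-positive cells were isolated by flow sorting. From these cells 1 library was made by chromatin immunoprecipitation for H3K4me3, a mark of active and poised promoters, and 1 for H3K27me3, the mark written by Polycomb repressive complex 2. The series is about how mesenchymal stem cells of the incisor become transit amplifying cells. Both libraries have the same age, dose and time in the labels, so the comparisons below are between the marks and between groups of genes. Whether both came from 1 sort or 1 set of pups was not established here. There was 1 library per mark and no input library was used, so no difference has a replicate check and no p-value is given. The values analysed are called islands of enrichment, each with a position and a summit height, and hold no read counts, so the depth of each library is unknown. Where low summits decide a result, it is also given for the higher-summit set, the 50% of each mark's islands with the higher summits. Intervals on shares of genes or islands are exact binomial (Clopper-Pearson) 95% intervals and cover counting over genes or islands only.

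The first comparison was of the extent and placement of the marks along the genome. The called islands of H3K27me3 were fewer and wider than those of H3K4me3. Island counts and widths also depend on depth and on the calling settings, which are unknown here for both libraries. There were 14361 H3K4me3 islands with a median width of 3.60 kb (interquartile range 2.40 to 5.00 kb), covering 56.8 Mb, and 11341 H3K27me3 islands with a median width of 6.20 kb (4.40 to 9.60 kb), covering 98.0 Mb. Islands over 20 kb numbered 666 for H3K27me3, or 5.87%, and 15 for H3K4me3. Among the 10 widest H3K27me3 islands were those on the Hox clusters, whose genes encode the homeodomain factors of axial patterning: Hoxc on chromosome 15 (102888001 to 103125599, 238 kb), Hoxa on chromosome 6 (52140601 to 52333399, 193 kb), Hoxb on chromosome 11 (144 kb) and Hoxd on chromosome 2 (141 kb). The others of the 10 covered Gfra1, a GDNF co-receptor, with the neighbouring Gm46650 (164 kb), Rhcg (149 kb), the neural factor gene Sox1 (133 kb) and Nfib (119 and 101 kb), and a stretch of chromosome 7 without protein-coding genes (131763601 to 131870999, 107 kb).

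The widest H3K4me3 island, 28.6 kb on chromosome 6 (6854801 to 6883399), covered Dlx5 and Dlx6, homeobox genes of jaw and tooth development. Also among the 10 widest were islands on the hedgehog receptor gene Ptch1 (26.0 kb), on Hand2 (25.2 kb) and on Sp7, an osteoblast and odontoblast transcription factor gene, together with the neighbouring Aaas (25.2 kb). H3K27me3 islands covered 91.6% of the Dlx5 and Dlx6 island, 13.8% of that on Ptch1, 100% of those on Hand2, on Foxf1 with Mthfsd (23.6 kb) and on Dlx1, Dlx2 and Metap1d (22.6 kb), and 0% of that on Sp7. Dense gene clusters were among the 10 widest as well: Pcyt2, Sirt7 and Mafg (23.8 kb), Car11, Dbp, Sphk2 and Rpl18 (23.8 kb), and Kifc5b, Phf1 and Cuta (21.8 kb). The highest H3K4me3 summits, in the authors' height units, stood at Atxn2l (278), Ptma (273), Hnrnpu (270), Eif4a1 with Senp3 (267) and Yy1 (265), genes used in most cell types, and none of these 5 islands overlapped H3K27me3. The highest H3K27me3 summits stood at the developmental factor genes Lmx1b (119) and Skor1 (114), at the Hoxd cluster with Evx2 (112), at Hic1 with Smg6 and Ovca2 (111), and in a gene-free island on chromosome 14 (19415601 to 19419799, 110). Heights are comparable within a mark only. Without an input library, high mappability or copy number at the gene-free island cannot be told from the mark.

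**Figure D1:**
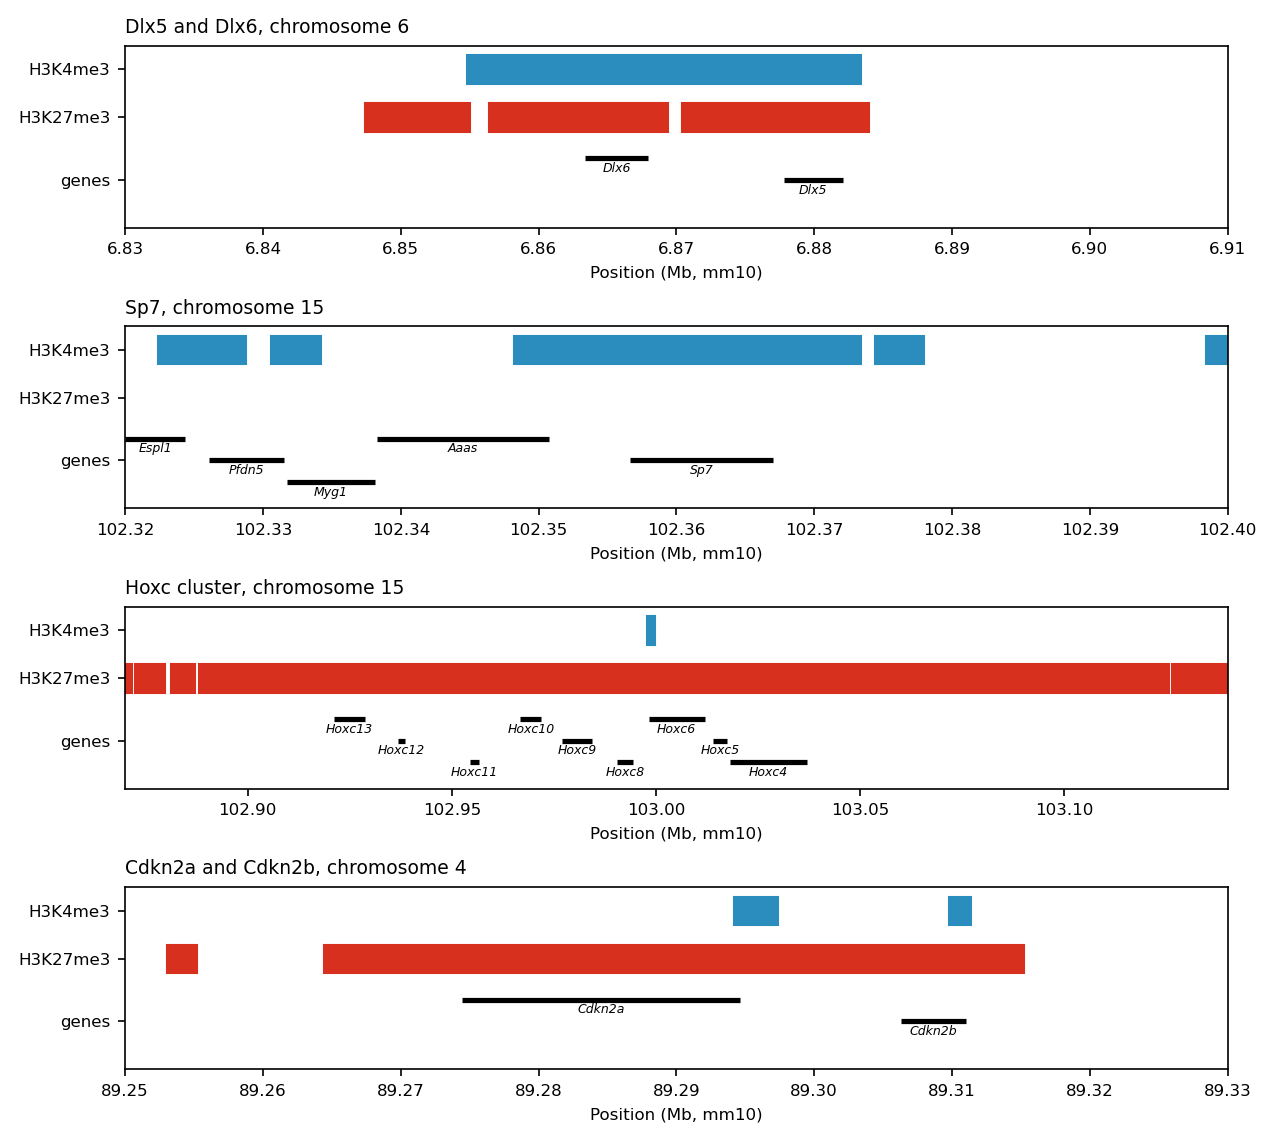
Islands of H3K4me3 (blue) and H3K27me3 (red) and annotated genes (black) at 4 loci, with the position in Mb (mm10) on the horizontal axis. Dlx5 and Dlx6 lie under a 28.6 kb H3K4me3 island that H3K27me3 islands cover to 91.6%, Sp7 under a 25.2 kb H3K4me3 island without H3K27me3, the Hoxc genes under a 238 kb H3K27me3 island, and Cdkn2a and Cdkn2b under a 50.8 kb H3K27me3 island.

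The X chromosome stood apart from the autosomes. It held 5.37 H3K27me3 islands per Mb, within the range of the autosomes (2.48 to 7.52), and 2.74 H3K4me3 islands per Mb, below the lowest autosome (3.83 on chromosome 14). There were thus 1.96 H3K27me3 islands per H3K4me3 island on X, against 0.553 to 0.952 on the autosomes. Summits on X were low for both marks, with a median height of 44 for H3K4me3 (76 or more on each autosome) and 9 for H3K27me3 (12 to 13). In the higher-summit set, X held 0.855 H3K27me3 and 0.240 H3K4me3 islands per Mb, below the lowest autosomes at 1.36 and 1.99, and there were 3.56 H3K27me3 islands per H3K4me3 island, against 0.549 to 1.01 on the autosomes.

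**Figure D2:**
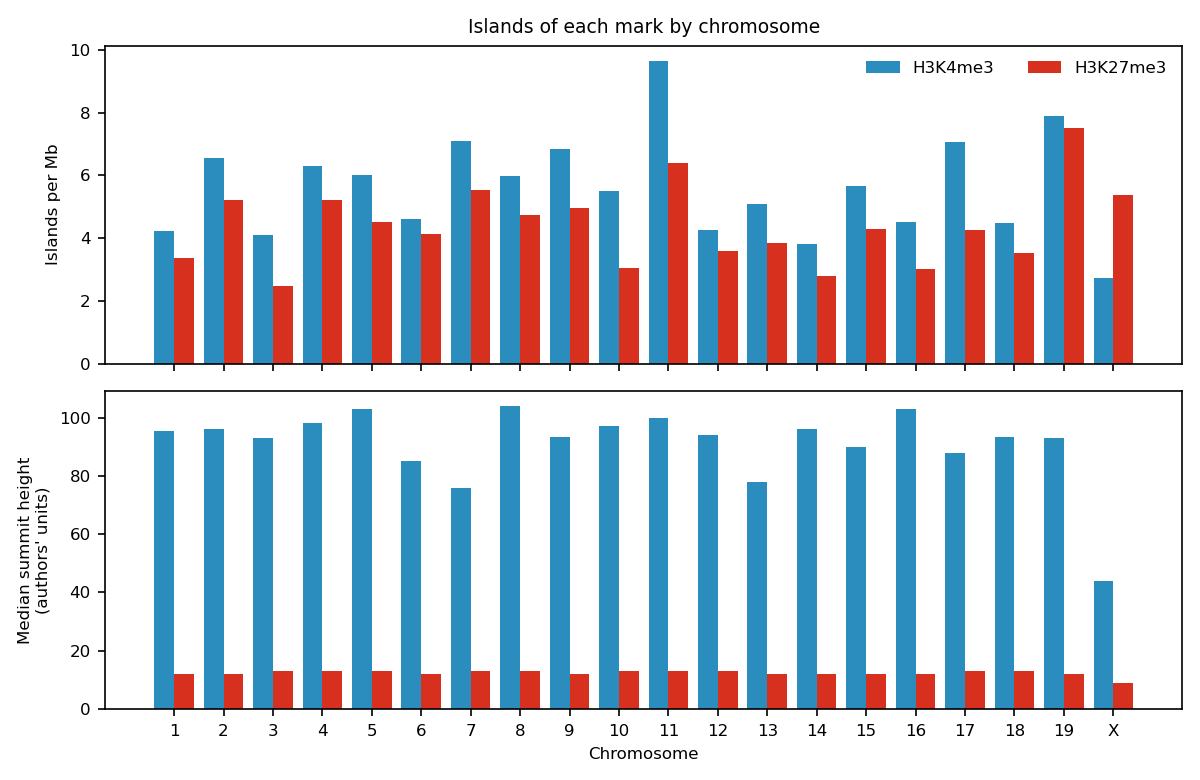
Islands per Mb (upper panel) and median summit height in the authors' units (lower panel) of H3K4me3 (blue) and H3K27me3 (red) on each autosome and X. X has 2.74 H3K4me3 islands per Mb against 3.83 on the lowest autosome, and its median H3K27me3 height is 9 against 12 to 13.

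Whether the activating and the Polycomb mark met at the same places was asked next. At 4198 H3K4me3 islands (29.2%) there was overlap with H3K27me3, and 3922 H3K27me3 islands (34.6%) overlapped H3K4me3. The shared sequence came to 11.9 Mb, which is 20.9% of the H3K4me3 length and 12.1% of the H3K27me3 length. When the H3K27me3 islands were placed at random on their own chromosomes 1000 times, the shared length had a median of 2.30 Mb. The lowest and highest of all placements were 2.02 and 2.60 Mb. The observed length was thus 5.17 times the median of random placement. The ratio was 2.77 in the higher-summit set, where 732 H3K4me3 islands overlapped H3K27me3. Random placement ignores that both marks favour gene-rich sequence.

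Protein-coding genes were then sorted by the marks within 1 kb of either annotated gene end. Of 21631 genes, 9116 (42.1%, interval 41.5 to 42.8%) carried H3K4me3 only, 3630 (16.8%, 16.3 to 17.3%) carried both marks, 1226 (5.67%, 5.36 to 5.98%) carried H3K27me3 only and 7659 (35.4%, 34.8 to 36.1%) carried neither. Genes with H3K4me3 carried H3K27me3 more often than genes without it, at 28.5% (27.7 to 29.3%) against 13.8% (13.1 to 14.5%), an odds ratio of 2.49. The direction of this relation depended on low summits: in the higher-summit set the odds ratio was 0.528, with 959 genes carrying both marks and 2771 H3K27me3 only. Of the 3630 genes with both marks, 3399 (93.6%) had them at the same gene end and in 3334 (91.85%) the islands shared sequence there. Among genes over 10 kb long with H3K4me3, 92.5% had it at 1 end only.

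The H3K4me3 islands of genes with both marks were lower than those of genes with H3K4me3 only, with a median height of 66 (interquartile range 31 to 115) against 126 (86 to 160), and a median width of 3.40 kb (2.20 to 5.00 kb) against 4.40 kb (3.20 to 5.80 kb). H3K27me3 islands had a median width of 8.40 kb both at genes with both marks and at genes with H3K27me3 only, and median heights of 24 and 20. The order of the H3K4me3 widths turned in the higher-summit set, to 5.00 kb at genes with both marks and 4.60 kb at genes with H3K4me3 only. An island missing from these lists was not read as absence of the mark, since 5 of 37 genes of cytoplasmic ribosomal proteins, Rpl3, Rpl7a and Rpl15 among them, had no H3K4me3 island within 1 kb of an end.

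The states of 24 gene lists were compared with those of 10000 random lists of the same size drawn from all protein-coding genes. A percentile gives the place of a list's share of marked genes among the shares of the random lists and describes these 2 libraries. Of the 48 percentiles, 31 lay outside the middle 95% of random lists, where 2.4 would be expected for lists drawn at random from all genes. The lists were chosen by function, some as comparators, and were not matched on promoter CpG content. The excess therefore has no reading specific to these cells. Some genes stand in more than 1 list, and neighbouring genes can share an island. Both marks can also lie at opposite ends of a gene. They lay at the same end in 3 of the 4 kinase inhibitors with both marks, 8 of 9 hedgehog and 10 of 11 Notch genes. The same held for 6 of 7 glia and nerve genes, 1 of 2 pluripotency genes and 1 of 2 tissue-restricted genes. In the other lists every gene with both marks had them at the same end, though at Rpl5 the islands shared no sequence. States refer to the gene ends: of the genes named below without H3K27me3, Runx2, Gli2, Sox5, Ibsp, Myh3, Ddx4 and Alb had an H3K27me3 island inside the gene, and of those without H3K4me3, Pax6, Nkx2-2, Hoxa3, Esam, Plvap, Gfap and Esrrb had an H3K4me3 island there.

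**Figure D3:**
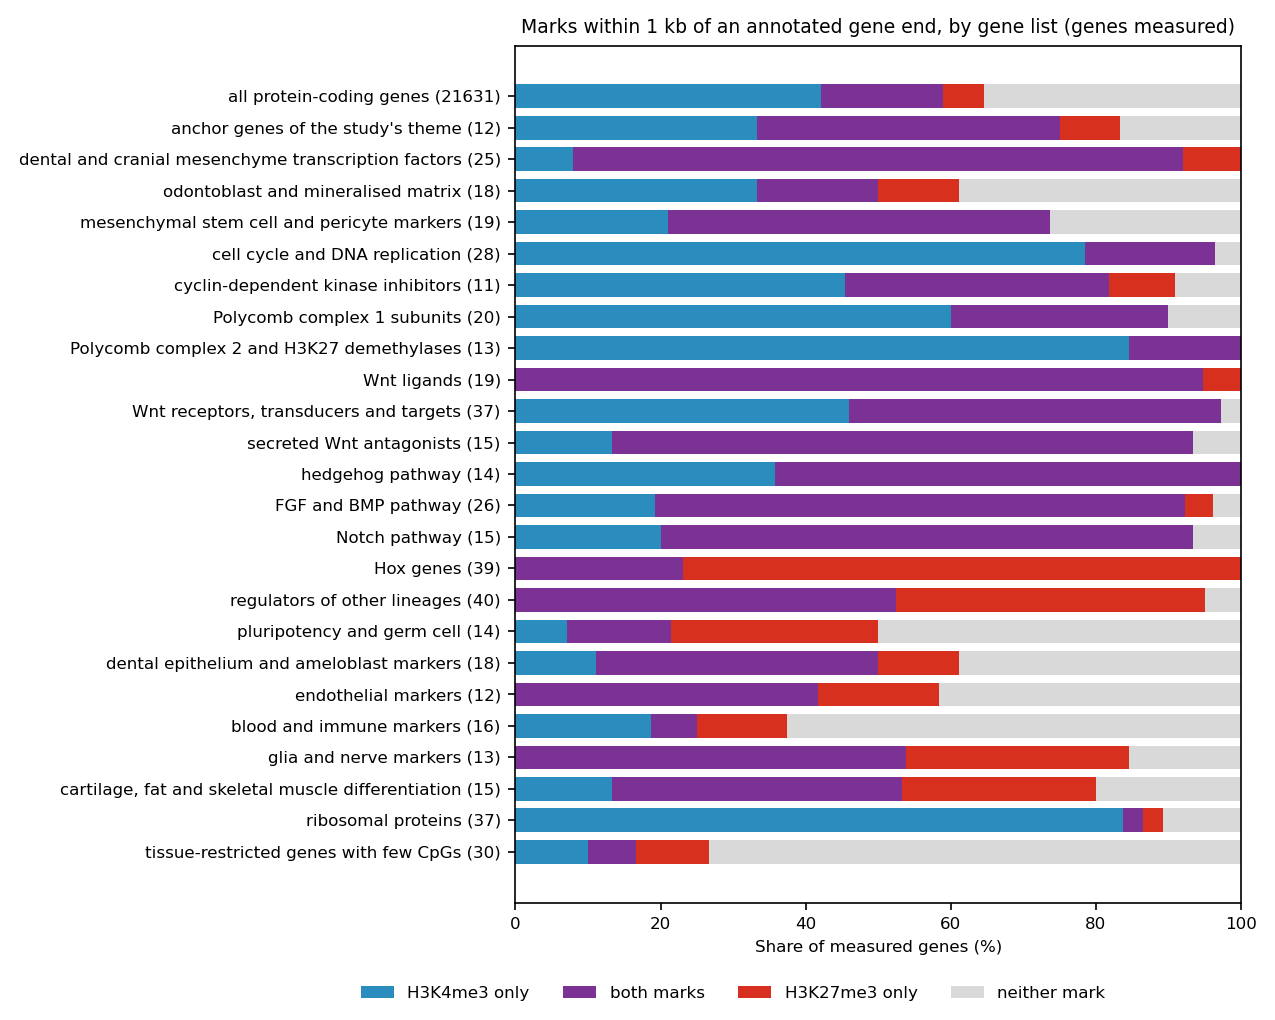
Share of measured genes (horizontal axis, percent) with H3K4me3 only, both marks, H3K27me3 only or neither mark within 1 kb of an annotated gene end, for all protein-coding genes and 24 lists, with the number of genes measured in parentheses. Both marks are found at 84.0% of the dental and cranial mesenchyme factors and 94.7% of the Wnt ligands, against 16.8% of all genes.

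Transcription factors of dental and cranial mesenchyme carried both marks at 21 of 25 genes (84.0%), and their H3K4me3 islands were wide. Msx1 lay under 14.0 kb of H3K4me3 (height 159) and 26.4 kb of H3K27me3 (height 26), Msx2 under 17.6 and 6.2 kb, Pax9, needed for tooth bud mesenchyme, under 11.4 and 35.8 kb, and Lhx6 under 4.60 and 29.2 kb. Runx2 and Klf4 carried H3K4me3 only, and Pax3 (93.6 kb) and Tfap2b (43.8 kb), which act in the early neural crest, H3K27me3 only. The shares with H3K4me3 and with H3K27me3 were 92.0% each, at percentiles 99.98 and 100. The median H3K4me3 width was 11.4 kb and the median H3K27me3 width 20.6 kb, both at percentile 100 among random lists of genes with that mark. Both marks stayed at 17 of the 25 genes in the higher-summit set.

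Among regulators of other lineages, such as neural, gut, heart and muscle fates, H3K27me3 lay at 38 of 40 genes (95%, percentile 100) with a median width of 39.7 kb, and H3K4me3 at 21 (52.5%, percentile 21.0) with a median width of 2.80 kb (percentile 0.40). All 21 carried H3K27me3 as well, a share with both marks at percentile 100. With H3K27me3 at 38 of the 40 genes, most of any 21 would carry it, so this percentile mainly restates the H3K27me3 share. Pax6, Nkx2-2, Nkx2-5 and Pax7 carried H3K27me3 only, over 49.0, 34.8, 56.8 and 71.6 kb. Neurog1, Neurog2 and Neurod1 carried both marks, with H3K4me3 islands of 1.80 to 3.40 kb, and the muscle genes Myf5 and Myog carried neither. Hand2, listed here for the heart and also used in jaw mesenchyme, had the widest H3K4me3 island of the list at 25.2 kb. In the higher-summit set, 2 of the 40 genes carried both marks. The percentile of the H3K4me3 share moved between 0 in that set and 72.9 among genes with no other gene at their ends, so the share alone did not set this list apart.

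Set against each other, the dental and the other-lineage factors had H3K27me3 at 92.0% and 95% of genes, a difference at percentile 32.8 among 10000 random splits of the pooled genes that did not stand apart. H3K4me3 differed in share (92.0% and 52.5%, percentile 99.94) and in median width (percentile 100). Median H3K27me3 widths also differed (20.6 and 39.7 kb, percentile 0.02). Median summit heights differed in opposite directions: 135 against 21 for H3K4me3 (percentile 100) and 20 against 82.5 for H3K27me3 (percentile 0). The 39 Hox genes lay under 5 H3K27me3 islands, 30 with H3K27me3 only, Hoxa2, Hoxa3, Hoxa5 and Hoxa6 among them, and 9 with a further H3K4me3 island of 2.0 kb at the median, Hoxa4, Hoxa7 and Hoxa13 among them. Their H3K4me3 share was 23.1% (percentile 0) and their H3K27me3 share 100% (percentile 100). No Hox gene had H3K4me3 in the higher-summit set. These comparisons of list pairs were chosen after the lists' counts had been seen.

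**Figure D4:**
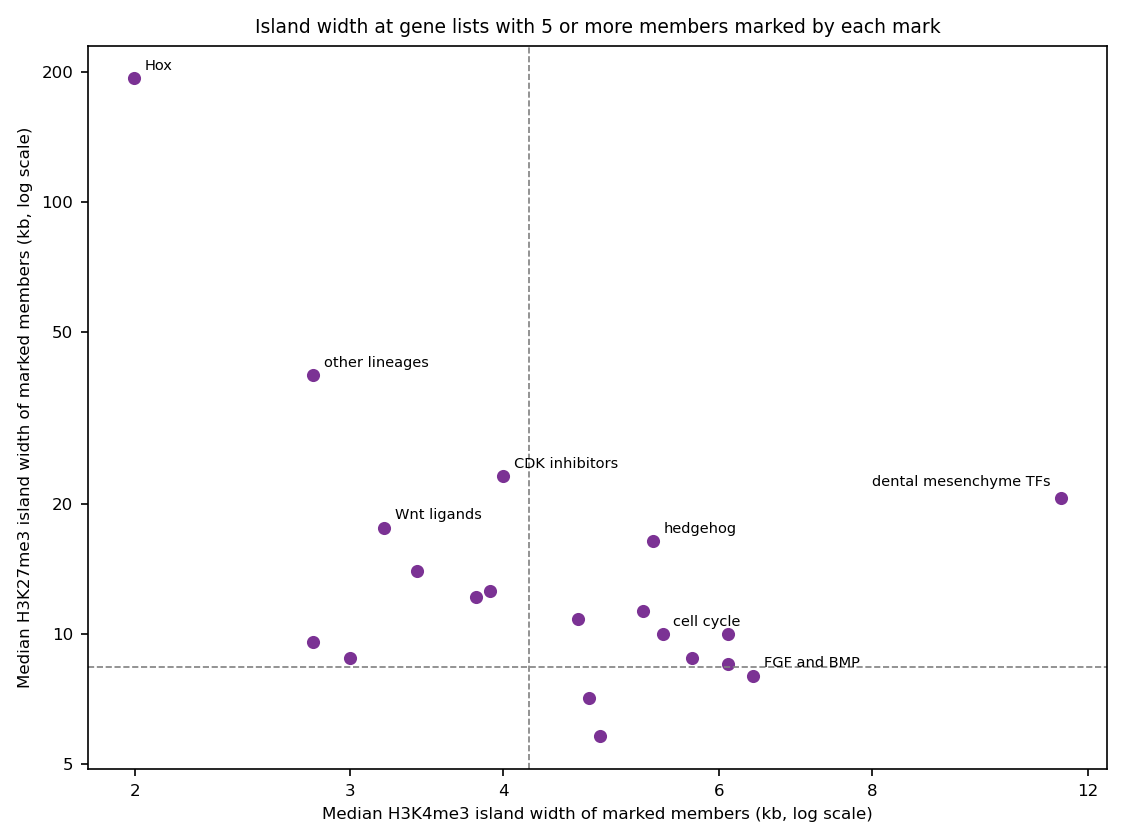
Median H3K4me3 width (horizontal axis, kb, log scale) against median H3K27me3 width (vertical axis, kb, log scale) of marked members, for each list with at least 5 members carrying each mark; dashed lines are the medians of all marked genes, 4.20 and 8.40 kb. The dental mesenchyme factors lie at 11.4 and 20.6 kb, the regulators of other lineages at 2.80 and 39.7 kb, and the Hox genes at 2.0 and 193 kb.

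Among 12 anchor genes of the study's theme, the genes of the Polycomb complex 1 ubiquitin ligases Rnf2 (2.80 kb) and Ring1 (14.2 kb), of the H3K27 methyltransferase Ezh2 (5.2 kb) and of the surface antigen Thy1 (5.00 kb) carried H3K4me3 only. Both marks were found at the Polycomb gene Bmi1 (7.6 kb of H3K4me3, 21.8 kb of H3K27me3), at Cdkn2a (3.20 and 50.8 kb), at Ccnd1, which encodes cyclin D1 (8.0 and 2.20 kb), at the hedgehog effector gene Gli1, a marker of incisor stem cells (8.0 and 12.2 kb), and at the proliferation marker gene Mki67 (5.00 and 10.4 kb, with an H3K27me3 height of 9). Cdkn1a, which encodes p21, carried H3K27me3 only (9.0 kb), and Axin2, a Wnt target, and Dspp, the odontoblast matrix gene, carried neither at their ends. Inside the gene, away from its ends, Axin2 and Cdkn1a did have an H3K4me3 island, and Dspp had none. The list's share with H3K27me3, 50%, lay at percentile 97.9, and the share with H3K4me3, 75%, at 86.1. Neither call was firm: H3K27me3 fell to percentile 75.4 among genes with no other gene at their ends, and H3K4me3 reached 98.3 when islands anywhere in the gene were counted.

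The Polycomb genes themselves were mostly marked by H3K4me3. Among 20 subunits of Polycomb complex 1, 12 carried H3K4me3 only, including Pcgf2 (13.8 kb) and Pcgf3 (4.40 kb), and 6 carried both marks, Bmi1, Pcgf5, Cbx2, Cbx8 and Rybp among them, with H3K27me3 islands from 2.20 kb at Rybp to 28 kb at Cbx8. Pcgf1 and Cbx7 had neither mark at their ends, and Cbx7 had both inside the gene. Among 13 genes of complex 2 and the H3K27 demethylases, 11 carried H3K4me3 only, such as Ezh1, Eed and Suz12, and both marks were found at Phf19 and at the demethylase gene Kdm6b, whose H3K4me3 island was 19.2 kb wide. The H3K4me3 shares of 90.0% and 100% lay at percentiles 99.8 and 99.9, and the H3K27me3 shares of 30.0% and 15.4% at 78.2 and 29.5. Both marks lay at 6 of the 20 genes and at 0 of the 13 in the higher-summit set.

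Genes of the cell cycle and DNA replication carried H3K4me3 at 27 of 28 members (96.4%, percentile 100), with a median width of 5.40 kb (percentile 99). H3K4me3 alone was found at 22, among them the cyclin genes Ccne1 (5.2 kb), Ccna2 (3.40 kb) and Ccnb1 (3.40 kb) and the mitotic kinase gene Cdk1 (5.6 kb). Both marks were found at Mki67, Ccnd1, Ccnd2 (18.4 kb of H3K27me3), Cdk4 and Cdk6, and the helicase gene Mcm4 had neither. The H3K27me3 share was 17.9% (percentile 29.2).

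Of 11 inhibitors of cyclin-dependent kinases and related brakes on the cycle, both marks were found at Cdkn2a, Cdkn2b, Cdkn1c and Cdkn2c. Cdkn2a and Cdkn2b lay under a single H3K27me3 island of 50.8 kb on chromosome 4 (89264401 to 89315199, height 73), with separate H3K4me3 islands of 3.20 and 1.60 kb. Cdkn1c, an imprinted gene, lay under 23.2 kb of H3K27me3. Cdkn1b (11.4 kb), Rb1, Rbl1, Rbl2 and Trp53 (10.2 kb) carried H3K4me3 only and Cdkn2d neither mark. The shares with H3K4me3 (81.8%) and H3K27me3 (45.5%) lay at percentiles 93.2 and 95.1, within the limits, and reached 97.6 and 98.8 among genes with no other gene at their ends. Both marks lay at 2 of the 11 genes and H3K27me3 only at 3 in the higher-summit set, with the H3K27me3 share at percentile 98.25. Against the cell cycle list, the H3K27me3 share lay at percentile 94.8 of random splits and did not stand apart.

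All 19 Wnt ligand genes carried H3K27me3 (percentile 100), and 18 carried H3K4me3 as well (94.7%, percentile 99.98). Wnt1 had 27 kb of H3K27me3 (height 92) and 3.20 kb of H3K4me3 (height 9), Wnt2 had 8.60 and 2.40 kb, Wnt2b 9.40 and 2.0 kb and Wnt3 55.8 and 2.20 kb, and Wnt8a carried H3K27me3 only (11.6 kb). Receptors, transducers and targets of the pathway carried H3K4me3 at 36 of 37 genes (97.3%, percentile 100) and H3K27me3 at 19 (51.4%, percentile 100). Fzd7, Fzd8 and the co-receptor genes Lrp5 and Lrp6 carried H3K4me3 only, and Fzd1, Fzd2, Fzd3 and Fzd4 both marks. Antagonists of the pathway, most but not all of them secreted, carried both marks at 12 of 15 genes, such as Dkk1, Dkk2, Sfrp1 and Sfrp2. Dkk3 and Sostdc1 carried H3K4me3 only and Dkk4 neither (shares 93.3% and 80.0%, percentiles 99.8 and 100).

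Against receptors and transducers, the ligands had H3K27me3 more often (percentile 100 of random splits), narrower H3K4me3 islands (median 3.20 against 5.70 kb, percentile 0.635), lower H3K4me3 summits (median height 25.5 against 136, percentile 0.0100) and higher H3K27me3 summits (57 against 27, percentile 98.6). The H3K4me3 share (94.7% against 97.3%, percentile 34.2) and the median H3K27me3 width (17.6 against 8.80 kb, percentile 95.4) did not stand apart. In the higher-summit set both marks lay at 2 of 19 ligands, 3 of 37 receptors and transducers and 3 of 15 antagonists. The H3K4me3 percentile was then 2.43 for the ligands and 39.0 for the antagonists.

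Other signalling pathways of tooth growth also carried both marks at many genes. In the hedgehog pathway, 9 of 14 genes did, including Shh (25.4 kb of H3K27me3), Ihh (49.0 kb), Dhh (17.8 kb) and Ptch1 (4.0 kb of H3K27me3 beside its 26.0 kb of H3K4me3), while Smo, Gli2, Gli3 and Sufu carried H3K4me3 only (shares 100% and 64.3%, percentiles 99.97 and 99.94). In the FGF and BMP pathway, 19 of 26 genes did, including Fgf3, Fgf10, Fgf8 and Fgf9. Fgfr1, Fgfr2, Id1, Id2 and Smad1 carried H3K4me3 only, Fgf20 H3K27me3 only and Inhba neither at its ends, with H3K4me3 inside the gene (shares 92.3% and 76.9%, both at percentile 100). In the Notch pathway, 11 of 15 genes did, including Notch3, Notch4, Jag2 and Dll1, while Notch1, Notch2 and Jag1 carried H3K4me3 only and Rbpj neither at its ends, with H3K4me3 inside the gene (shares 93.3% and 73.3%, percentiles 99.8 and 100). Both marks lay at 4, 5 and 4 genes of these lists in the higher-summit set, and the H3K4me3 share of the Notch list moved to percentile 95.8.

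Odontoblast and mineralised matrix genes were split. Col1a1 (10.6 kb), Col1a2 (4.40 kb), Sp7 (25.2 kb), Sparc (5.80 kb), Slc20a2 and Ccn4 carried H3K4me3 only, while Dspp, Dmp1, Ibsp and Bglap were among 7 of 18 with neither mark. Alpl, Nes and Enpp1 carried both marks, and Phex and Mepe H3K27me3 only with heights of 10 and 9. Shares of 50% with H3K4me3 and 27.8% with H3K27me3 lay at percentiles 21.9 and 71.3. In the higher-summit set 14 of the 18 genes carried neither mark, 3 H3K4me3 only and 1 both marks, and the H3K27me3 share moved to percentile 9.62.

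Mesenchymal stem cell and pericyte markers carried both marks at 10 of 19 genes, including Gli1, Celsr1, Pdgfra (11.6 kb of H3K4me3) and Pdgfrb. Thy1, Cspg4, Eng and Cd44 carried H3K4me3 only, and Axin2, Acta2, Rgs5, Ly6a and Vcam1 neither. The H3K4me3 share of 73.7% lay at percentile 89.6 and the H3K27me3 share of 52.6% at 99.8. In the higher-summit set both marks lay at 4 of the 19 and neither at 11, and the H3K4me3 share moved to percentile 7.28.

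Markers of epithelial, endothelial and blood cells, which a sort of pulp cells could also hold, had no H3K4me3 island in the higher-summit set. Of 18 dental epithelium and ameloblast genes, Krt14 and Ambn carried H3K4me3 only (heights 8 and 15), Epcam, Cdh1 and Sox2 were among 7 with both marks, Klk4 and Cldn4 carried H3K27me3 only, and Krt5, Trp63, Amelx and Enam were among 7 with neither. Of 12 endothelial genes, Kdr, Erg, Sox17, Sox18 and Cldn5 carried both marks, Esam and Plvap H3K27me3 only, and Pecam1, Cdh5, Tek, Tie1 and Emcn neither. Of 16 blood and immune genes, Cd68, Spi1 and Klf1 carried H3K4me3 only, Tal1 both marks, Cd3e and C1qa H3K27me3 only, and Ptprc, Csf1r, Adgre1 and Itgam were among 10 with neither. H3K4me3 shares were 50%, 41.7% and 25% (percentiles 22.2, 12.8 and 0.435) and H3K27me3 shares 50%, 58.3% and 18.8% (percentiles 99.4, 99.6 and 37.6). The H3K4me3 shares of the epithelial and endothelial lists moved in the higher-summit set to percentiles 0.0050 and 0.20.

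Of 13 glia and nerve genes, Foxd3, Erbb3 and Mbp were among 7 with both marks, Sox10 (19.2 kb), Stmn2, Snap25 and Gfap carried H3K27me3 only, and S100b neither. Of 15 genes of cartilage, fat and muscle differentiation, Sox9 (11.0 kb of H3K4me3), Col2a1, Acan, Sox6, Pparg and Cebpa carried both marks, Sox5 and Plin1 H3K4me3 only, Adipoq, Ckm, Acta1 and Des H3K27me3 only, and Fabp4, Myh3 and Ttn neither. H3K4me3 shares of 53.8% and 53.3% lay at percentiles 34.6 and 32.6, and H3K27me3 shares of 84.6% and 66.7% at 100 and 99.98. In the higher-summit set both marks lay at 0 of 13 and 1 of 15 genes and H3K27me3 only at 10 and 8, and the H3K4me3 shares moved to percentiles 1.22 and 2.67. Of 14 pluripotency and germ cell genes, Pou5f1, Nanog, Esrrb and Tdgf1 carried H3K27me3 only, Sox2 (50.2 kb) and Lin28a both marks, Dazl H3K4me3 only, and Zfp42, Dppa3, Dppa5a and Ddx4 were among 7 with neither (shares 21.4% and 42.9%, percentiles 0.230 and 95.6). None of these 14 genes had H3K4me3 in the higher-summit set.

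Of the comparator lists, ribosomal protein genes carried H3K4me3 at 32 of 37 members (86.5%, percentile 99.99) and H3K27me3 at 2, Rpl5 among them (5.41%, percentile 0.380). Rpl4, Rpl6, Rpl7 and Rpl8 were among 31 with H3K4me3 only. Of 30 tissue-restricted genes with few CpGs, 22 carried neither mark, such as Alb, Cyp2e1, Cyp7a1 and Ins2. Apoa1, Apoa2 and Sftpc carried H3K4me3 only, Krt10 and Lor both marks, and Krt71, Aqp2 (59.8 kb) and Prm1 H3K27me3 only (shares 16.7% each, percentiles 0 and 23.8).

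The placement of the marks away from genes was compared last. No protein-coding gene end lay within 1 kb of 6959 of 11337 H3K27me3 islands (61.4%, interval 60.5 to 62.3%) and of 3228 of 14359 H3K4me3 islands (22.5%, 21.8 to 23.2%) on autosomes and X. Of these distant islands, 2846 of H3K27me3 (40.9%) and 1938 of H3K4me3 (60.04%) lay inside a protein-coding gene, and 2877 (41.3%) and 645 (19.98%) outside all annotated genes. Distant islands were lower than those near gene ends, with a median height of 28 against 107 for H3K4me3 and 11 against 20 for H3K27me3. Exons and introns were not analysed here.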

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

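The tests of low summits, of the ratio near gene ends and of an inactive X below, and both tests of ribosomal protein genes, were chosen only after the result was seen. The Y chromosome, which no comparison between genes used, held 4 H3K27me3 islands (7024801 to 7031599, 90738201 to 90740599, 90801801 to 90806199 and 90807401 to 90812799, heights 9 to 15) and 2 H3K4me3 islands (1244801 to 1246199 and 1285001 to 1286999, heights 16 and 10).

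H3K27me3 islands on the X chromosome were many relative to H3K4me3 (1.96 per H3K4me3 island, at most 0.952 on an autosome) and low. Gene-poor sequence does not account for all of it: among islands within 1 kb of a protein-coding gene end the ratio on X was 0.607 (227 to 374 islands, interval 0.512 to 0.718, from that of the share), above the highest autosome (0.456). A part in it stays open, since 24.8% of the X islands lay near such an end, below the lowest autosome (32.5%), but chromosome 12, also with 5.66 genes per Mb, had 37.0% and a ratio of 0.841. Calls of low height stay open too: in the higher-summit set the ratio on X was 3.56, above the highest autosome (1.01), but summits of both marks are low on X, so a filter on height sets both counts and decides nothing. An inactive X in female cells of the pool could also contribute. Of the H3K4me3-marked X genes, 37.7% carried H3K27me3 (152 of 403, interval 33.0 to 42.7%). The interval reaches the highest autosome (33.2%), so this stays open. The sex of the pups is not given in the sources used here, and the Y islands listed above do not give the share of male cells. The number of X copies per cell in the pool is therefore unknown, and its part in the low summits was not tested.

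Dental and cranial mesenchyme factors paired both marks with wide H3K4me3 islands. Another protein-coding gene within 1 kb of an end does not account for the share with both marks. Among the 22 members without such a neighbour, that share lay at percentile 100. Wide islands that reach in from genes farther away were not removed there, so their part stays open. Islands joined across genes do not account for the H3K4me3 widths. The 18 members whose island reaches no other gene had a median width of 10 kb against 3.60 kb for all such genes (percentile 100). Nor is this width shared by genes with both marks in general, as the 21 members with both marks had 11.4 kb against 3.40 kb (percentile 100). A candidate explanation is that these factors are active in some sorted cells and Polycomb-marked in others, or carry both marks in the same cells; nothing here tells these apart, and no biological explanation was tested.

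Of the ribosomal protein genes, 5 had no H3K4me3 island, Rpl3, Rpl7a and Rpl15 among them, although 32 others did. Misplaced annotated ends stay open: 0 of these 5 genes had an island between their ends, but at most 3.625 kb lay there outside the windows already searched, and the nearest islands, 3.89 to 27.4 kb away, could mark a start outside the annotated gene. Weak signal just below the calling threshold stays open: the lowest marked member had a height of 93, where the 10th percentile of all H3K4me3 islands is 16, but no signal value was analysed at the unmarked genes. A loss of islands before deposition was not tested, and it might affect other genes called unmarked.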

How the results depend on the processing

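The whole-gene and free-end alternatives were added after seeing the data, and the cause of each change was not tested except where stated. Of 288 recomputed list percentiles, 267 kept their side of the limits, 13 passed them, 6 no longer did, and 2 moved from above the upper limit to below the median of random lists, of which 1 went below the lower limit.

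The higher-summit set changed most, in part by construction, since it keeps 7180 H3K4me3 and 5670 H3K27me3 islands. Overlapping islands numbered 732 and 735, the ratio to random placement was 2.774, 959 genes carried both marks and 2771 H3K27me3 only, and the odds ratio reversed to 0.528; it was 1.643 with the window covered to 50% or more and 2.24 to 3.26 under the other alternatives. The order of median H3K4me3 widths turned, to 5.00 kb at genes with both marks and 4.60 kb with H3K4me3 only. H3K4me3 percentiles in this set were 2.43 for Wnt ligands and 38.96 for Wnt antagonists (inside the limits, on the other side of the median), 95.8 for Notch, 97.74 for anchor genes, 0 for other lineages, 0.005 for epithelium, 0.2 for endothelium and 1.215 for glia, and the H3K27me3 percentile of kinase inhibitors was 98.25.

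For anchor genes, H3K4me3 rose to 98.74 with 2.5 kb windows and 98.31 over the whole gene, and H3K27me3 no longer passed the limits at 94.08 (500 bp), 96.97 (2.5 kb), 96.48 (whole gene) and 75.37 (free ends). For kinase inhibitors, H3K4me3 passed at 98.14 (2.5 kb), 97.56 (whole gene) and 97.64 (free ends), and H3K27me3 at 98.8 (free ends). Pluripotency genes reached 97.89 for H3K27me3 over the whole gene, and blood markers 3.865 for H3K4me3 with free ends. Islands away from genes were 16.32% (any annotated gene) and 16.97% (5 kb) for H3K4me3, and 49.8% and 53.87% for H3K27me3.

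No paired analysis was possible because there is 1 library per mark. Not run, for want of strand, transcripts and sequence here, were the 5'-most start site, lists matched on promoter CpG content, and placement outside assembly gaps. Depth is unknown, so an absent island cannot be told from a shallow library.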

Other observations

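Gene families, picked by symbol after their values had been seen, separated further. Of 1110 olfactory receptor genes (Olfr) 1103 carried neither mark, as did 354 of 355 vomeronasal receptor genes (Vmn1r and Vmn2r) and 41 of 42 beta-defensin genes (Defb). Potassium channel genes (Kcn) carried H3K27me3 at 70 of 94 members (74.5%, percentile 100), 49 of them with H3K4me3 as well, and receptors for GABA and glutamate at 36 of 46 (78.3%, percentile 100). Keratin genes carried H3K27me3 at 22 of 53 (41.5%, percentile 99.9) and H3K4me3 at 6 (percentile 0). Collagen genes carried H3K27me3 at 25 of 44 (56.8%, percentile 100) and H3K4me3 at 32 (72.7%, percentile 97.0).

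Among transcription factor families, forkhead genes carried both marks at 25 of 44 members, Sox genes at 12 of 19 and T-box genes at 6 of 13, with median H3K27me3 widths of 23.8, 19.5 and 22.2 kb. Zinc finger genes (Zfp) carried H3K4me3 only at 281 of 397 members and H3K27me3 at 49 (12.3%, percentile 0). Protocadherin genes carried H3K4me3 at 32 of 69 (46.4%, percentile 1.62) and H3K27me3 at 14 (20.3%, percentile 34.9). Proteasome and mitochondrial ribosomal genes carried H3K4me3 only at 31 of 40 and 69 of 78 members. Members of a family often lie side by side and can share islands.

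Some of the highest H3K27me3 summits lay where no gene is annotated: chromosome 14 (19415601 to 19419799, height 110), of which 3799 bp were shared with H3K4me3, chromosome 8 (15519001 to 15520199, height 109) and chromosome 10 (42606801 to 42638999, height 79). The first of these islands was 4199 bp wide in all. The second was 1199 bp wide, below the 5th percentile of H3K27me3 widths (2999 bp). Without an input library, high mappability or copy number at these places cannot be told from the mark. These positions were picked after their values were seen.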
